A study of Oryza sativa Japonica Group with 74 samples.

How the data were processed

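Values are the deposited gene counts and TPM of 74 libraries (75 columns in each table, 37849 genes). Per the labels, reads were aligned with HISAT2 and assembled with StringTie on IRGSP-1.0, with no versions given, after RNA extraction with RNeasy and library preparation with NEBNext Ultra II Directional. The count columns hold raw counts, whole numbers, as deposited. TPM columns hold TPM by the authors, whose sums per library run from 0.985 to 0.997 M. One deposited column, replicate 1 of elf3-1 elf3-2 at ZT14 LD, is not a library of its own: it is the mean of replicates 2 and 3 in all 37849 genes, within 0.5 counts or 0.001 TPM, and was left out. The 6 WT libraries labelled ZT24 carry the name ZT00 in the tables and were matched on it. Groups were taken from the labels alone: 25 groups, 24 of 3 libraries and 1 of 2. Library totals ran from 25.7 to 74.1 M (second highest 51.8), and the 20 most abundant genes took 3.14 to 9.13% of counts.

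Differences were tested with edgeR 4.0.16 in R 4.3.3: 1 fit of all 74 libraries with a mean per group, TMM factors (0.808 to 1.21), filterByExpr (28912 genes kept, 8937 left out), glmQLFit with robust estimation and glmQLFTest. The fit had 49 residual degrees of freedom and a median of 3.15 prior ones. Adjusted p values are Benjamini-Hochberg over all tested genes of a comparison, with 0.05 as threshold, and all adjusted p in the report are from edgeR for genes and from camera for lists. Genotype averages weigh the 6 conditions alike; time of day, day length over all times and interactions are F tests over several contrasts. CPM use TMM scaled totals. Standard errors of log2 fold changes come from the quasi-likelihood fit. DESeq2 1.42.0 and limma 3.58.1 (trend on log2 TPM plus 1 or 0.1, genes of at least 1 TPM in at least 2 libraries) were run as other tools, and where the text gives limma 2 counts, they are for 1 and 0.1 in this order. Replicate numbers were not used as pairs.

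Gene lists were written before the data were examined, as were the comparisons, tools and settings other than those named below as chosen later. The 17 lists (144 genes) are evening complex, clock, flowering activators, flowering repressors, photoreceptors and light signalling, light harvesting, chlorophyll synthesis, starch and sucrose (called starch), gibberellin, cell wall loosening, nitrogen assimilation, defence, cold and drought, heat shock, root, dividing cell and meristem (called dividing cell) and reference genes. Symbols come from these hand lists, matched by identifier. All 144 identifiers are in the count table; 81 symbols are in a RefSeq gene table, 78 of them on the chromosome that the identifier names, and the 3 others were dropped, leaving 141. List tests are camera on voom values with a preset inter-gene correlation of 0.01, lists of at least 3 tested genes, adjusted over 374 list tests: 47 passed, 9 of which also passed with an estimated correlation. Where list members passed, the median and the test also differed in sign for nitrogen in the elf3-1 elf3-2 average, photoreceptors (phyB ZT18 LD), gibberellin (phyB ZT18 SD, lux over elf3-1 elf3-2), cold and drought (lux over WT) and defence (lux over elf3-1 elf3-2). In mutant comparisons a list not named had no member and no list test past the threshold. "Alone" after a count gives genes passing when adjusted over the list alone. The results of 2 listed genes are not reported here, while counts over lists and over all genes include them.

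Genes were named by a rule: the mutated genes in every group; list members past the threshold, up to 4 per list by size of change; clock, evening complex and flowering genes where useful; and the largest consistent rises and falls with a symbol or product. Because the files give no symbol for any of those largest changes, they are counted among the named genes where the text says how many stayed past the threshold, and are not otherwise named. For time of day the rule takes clock and flowering genes with the time of the highest mean, and for interactions list members past the threshold. The 4 interaction genes were named after their values were seen.

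Tests and settings chosen after the data were seen are the marker positions (thinned ones too), the 17 doubted libraries and the counts without them, estimateDisp first, leaving out ZT24, neighbours on chromosomes and the tissue marker counts per library. Distances between libraries use the 3000 most variable genes. A position is the median over markers of the place between the mean of the other genotypes (0) and of the mutant (1) at ZT18. No library was moved to another group. Effect correlations are across tested genes, with counts simulated without effects against the same controls (10 simulations) and a jackknife over libraries. Overlaps are set against the product of the 2 counts over all tested genes.

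The procedure was run on simulated counts in which 100 genes were changed. For elf3-1 elf3-2 at ZT18 SD edgeR recovered 54% of genes changed 2-fold and 91% changed 4-fold, with 8 unchanged genes called. Fitting the 6 libraries alone recovered 19% and 72% (11 called), DESeq2 58% and 92% (35 called), limma-trend 51% and 90% (6 called), time of day in SD 68% and 87% (41 called) and the elf3-1 elf3-2 interaction 26% and 71% (6 called). Camera gave a raised list an adjusted p = 2.42e-50 and called 0 of 50 unchanged lists.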

Results

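The series asks how the Evening Complex, a clock protein complex of ELF3, ELF4 and LUX, passes photoperiod signals to flowering in rice. RNA was sequenced from whole plants labelled as 21 days old. They were wild type (WT, cultivar Nipponbare), a phyB mutant, an elf3-1 elf3-2 double mutant and a lux mutant, all named from the labels. Plants grew in long days (LD, 14 h light) or short days (SD, 10 h light) and were sampled at hours after lights on (ZT). WT covers 6 times in LD and SD (36 libraries). The phyB (18 libraries) and elf3-1 elf3-2 (17 libraries) groups cover ZT6, ZT14 and ZT18 in LD and SD, and lux (3 libraries) covers ZT14 SD alone. Every group has 3 libraries except elf3-1 elf3-2 at ZT14 LD, which has 2, since its replicate 1 column is the mean of the other 2. Library totals ran from 25.7 to 74.1 M counts (median 34.8 M), and 28912 genes were tested. Expression is given as CPM (counts scaled to the library total), as mean ± standard deviation (n = 3 unless stated), and log2 fold changes as mutant over WT or LD over SD with their standard error. These errors cover counting error and variation among libraries, and nothing that sets whole groups apart. A library at 0 is read as holding fewer than 3 counts, the floor, so for genes at 0 in a whole group CPM is given and no fold.

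At ZT18, where no library was doubted, genes with a gap above 1.5 log2 units between a mutant and the other genotypes were taken as markers: 46 higher and 1 lower in elf3-1 elf3-2, and 82 higher and 74 lower in phyB. A library's position is the median of its markers on a scale from 0 (the other genotypes) to 1 (the mutant). At ZT6 and ZT14, replicates 2 and 3 sat where their labels put them: the 8 libraries labelled phyB at 0.98 to 1 on the phyB scale, and the 8 labelled elf3-1 elf3-2 at 0.99 to 1.07 on the elf3-1 elf3-2 scale. Replicate 1 did not. The 4 replicate 1 libraries labelled WT lay at 0.99 to 1 on the phyB scale, the 4 labelled phyB at 0.96 to 1.04 on the elf3-1 elf3-2 scale, and the 3 labelled elf3-1 elf3-2 at 0.02 to 0.18 on it. Replicate 1 of WT at ZT10 and replicate 3 of WT at ZT2 SD and ZT24 (5 libraries) lay nearer another WT group than their own. The doubted set is defined by genotype, time and replicate number, so it also holds replicate 3 of WT at ZT2 LD, which did not stand apart (distance 1.37 to its own group and 1.75 to the nearest other). All counts below keep every library under its label, so each direction at ZT6 and ZT14 is drawn from libraries whose labels the data go against. Beside each total stands the count without these 17 doubted libraries, a choice made after the data were seen.

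**Figure D1:**
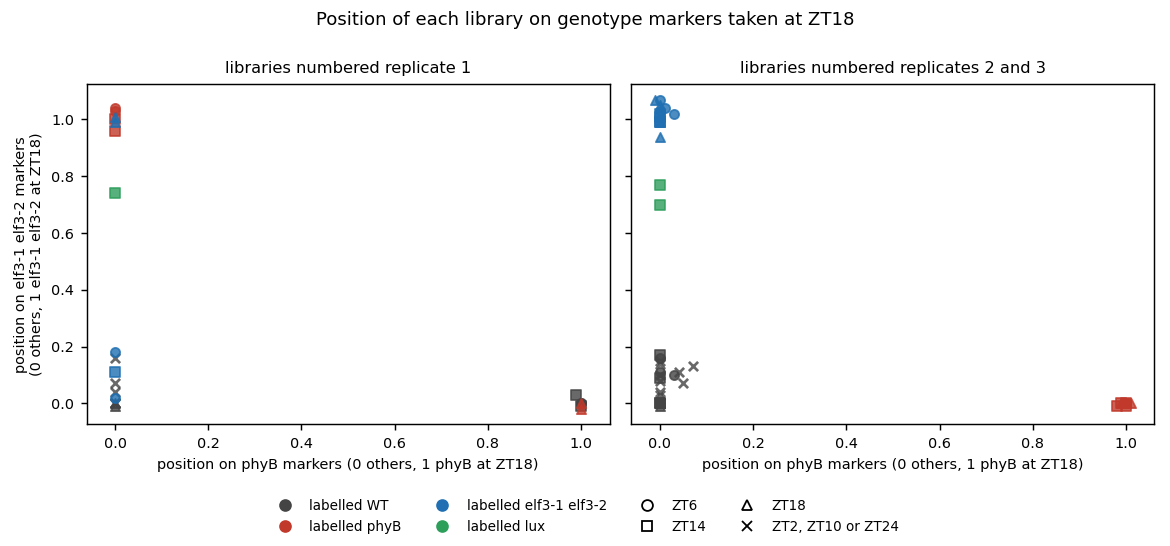
Position of each library on genotype markers taken at ZT18. Each point is 1 library; colours give the labelled genotype and shapes the time. The x axis is the median position on the phyB markers and the y axis on the elf3-1 elf3-2 markers, where 0 is the level of the other genotypes and 1 the level of the mutant at ZT18. The left panel holds libraries numbered replicate 1, the right panel replicates 2 and 3.

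The targeted genes were read first. ELF3-1 (Os06g0142600), the ELF3 gene expressed all day, stood in the elf3-1 elf3-2 libraries at 79.6 ± 19.2 CPM at ZT6 LD, 75.5 ± 31.9 at ZT6 SD, 53.5 ± 6.62 (n = 2) at ZT14 LD, 82.4 ± 6.84 at ZT14 SD, 69.2 ± 11.1 at ZT18 LD and 88.1 ± 11.6 at ZT18 SD. Its WT group means ran from 85 ± 7.51 (ZT10 SD) to 205 ± 34.5 (ZT24 SD) and its phyB means from 82.6 ± 12.9 to 149 ± 7.48. Averaged over 6 conditions ELF3-1 fell by 0.75 (SE 0.09, adjusted p = 1.91e-08). It fell by 0.91 at ZT14 SD (adjusted p = 0.0138), by 0.86 at ZT18 LD (adjusted p = 0.0359) and by 0.88 at ZT18 SD (adjusted p = 0.0251), and did not pass elsewhere. ELF3-2 (Os01g0566100) did not pass as lower in the double mutant in any condition. At ZT14 SD it stood at 80.8 ± 4.75 CPM against 116 ± 6.54 in WT (−0.52, adjusted p = 0.618; −0.54 and adjusted p = 0.0351 without the doubted libraries). Its means ran from 26.7 ± 13.9 to 94.8 ± 10.8 CPM against 8.63 ± 2.76 to 116 ± 6.54 in WT and 15.2 ± 8.2 to 89.3 ± 11.4 in phyB, and it rose by 1.92 at ZT6 LD (adjusted p = 0.00607). PHYB (Os03g0309200), the red light receptor, was still detected in the phyB groups, at 70.7 ± 1.64 to 118 ± 18.4 against 53.9 ± 2.24 to 182 ± 53.7 in WT and 85.4 ± 18.7 to 141 ± 0.732 (n = 2) in elf3-1 elf3-2. It fell by 0.32 averaged over conditions (adjusted p = 0.0067; 0.52 without the doubted libraries) and passed in no single condition. LUX (Os01g0971800) stood at 33.8 ± 2.81 in lux against 53.2 ± 5.49 in WT at ZT14 SD, a change that passed only without the doubted libraries (−0.65, adjusted p = 0.508; −0.7 and adjusted p = 0.0111 without them). Its means ran from 0.339 ± 0.178 to 147 ± 50.1 in WT, 7.47 ± 0.383 to 123 ± 38.9 in phyB and 16 ± 13.7 to 148 ± 23.5 (n = 2) in elf3-1 elf3-2. In lux, ELF3-1 stood at 65.2 ± 3.23, ELF3-2 at 58.1 ± 1.63 and PHYB at 79.2 ± 5.32, all lower than WT (log2 fold changes −1.24, −0.99 and −1.20, adjusted p = 1.5e-06, 0.0361 and 1.53e-06). Transcript abundance does not show whether a protein is made, so these values neither support nor exclude the mutations.

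WT time of day answers which genes follow the day in each photoperiod. The morning transcription factor LHY (Os08g0157600) peaked around dawn, the pseudo-response regulators PRR73 (Os03g0284100), PRR37 (Os07g0695100) and PRR95 (Os09g0532400) and the flowering regulator GIGANTEA (GI, Os01g0182600) peaked in the afternoon, TOC1 (Os02g0618200) and LUX had their highest means as lights went off, and ELF3-2 had its own in the dark. Differences in peak time between LD and SD were not tested, and every WT group outside ZT18 holds a doubted library (replicate 1 at ZT6, ZT10 and ZT14, replicate 3 at ZT2 and ZT24). Antenna genes such as CAB1R and LHCB2 were highest by day and near silent at ZT18. LHCB4 still stood at 222 ± 32.5 CPM at ZT18 LD, and LHCA6 was highest in the dark (72.3 ± 2.97 at ZT18 LD, 90.3 ± 23.3 at ZT14 SD). LHY was highest at ZT2 in LD (6140 ± 444 CPM) and ZT24 in SD (5590 ± 1380), and GI at ZT10 in LD and SD (2510 ± 621, and 3010 ± 143). PRR37 peaked at ZT10 in LD (326 ± 29.8) and SD (359 ± 22.8), and PRR73 at ZT10 in LD (1160 ± 145) and ZT6 in SD (1140 ± 319). TOC1 had its highest mean at ZT14 in LD (189 ± 56.9) and ZT10 in SD (284 ± 63.2), FKF1 at ZT14 (196 ± 62.4) and ZT10 (269 ± 57.2), and ELF3-2 at ZT18 (72.8 ± 1.68) and ZT14 (116 ± 6.54). LUX was highest at ZT14 in LD (147 ± 50.1), and in SD stood at 59.3 ± 39.6 at ZT10 and 53.2 ± 5.49 at ZT14. Among flowering genes, the repressor Hd1 peaked at ZT14 (18.5 ± 6.44, in LD and 19.2 ± 5.02, in SD), the LD repressor Ghd7 (Os07g0261200) at ZT2 (7.99 ± 0.904, in LD and 3.72 ± 2.13, in SD), and the florigen gene Hd3a at ZT6 in SD (3.61 ± 1.53). The antenna gene CAB1R (Os09g0346500) went from 4910 ± 1540 at ZT10 LD to 5.96 ± 1.16 at ZT18 LD. Time changed 16290 genes in LD (19483 without the doubted libraries, 15684 shared) and 20372 in SD (22040, 19701 shared). All 10 clock genes, 14 photoreceptor and light signalling genes, 14 light harvesting genes and 10 chlorophyll genes passed in LD and in SD. In LD and SD respectively, 3 and 4 of 4 evening complex genes passed, as did 5 and 8 of 10 flowering activators, 7 and 6 of 8 flowering repressors, 10 and 9 of 11 starch genes and 11 and 10 of 14 gibberellin genes. So did 5 and 5 of 6 cell wall genes, 2 and 2 of 4 nitrogen genes, 8 and 3 of 9 defence genes, 5 and 5 of 7 cold and drought genes, 2 and 1 of 3 heat shock genes, 3 and 2 of 6 root genes, 1 and 1 of 6 dividing cell genes and 3 and 2 of 3 reference genes.

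**Figure D2:**
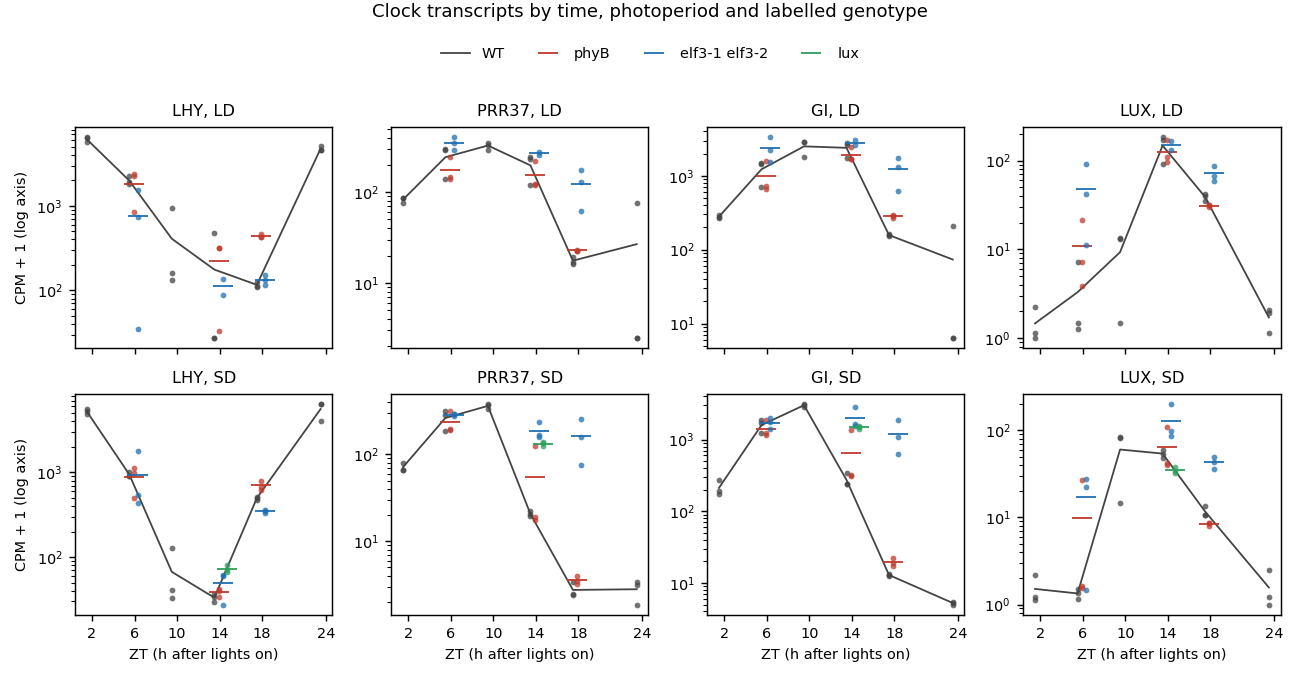
LHY, PRR37, GI and LUX in LD (top) and SD (bottom) against time after lights on. Points are single libraries under their labelled genotype, lines and bars are group means, and the vertical axis is CPM plus 1 on a log scale.

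WT LD against SD asks what day length alone changes. At ZT14 lights are just going off in LD but have been off since ZT10 in SD, and the clock genes PRR95, PRR73, PRR37, GI, FKF1 and TOC1, 12 of 14 light harvesting genes and 7 of 11 starch genes were higher in LD. Ghd7, which delays flowering in LD, was higher in LD, while the floral meristem gene MADS14 and the nitrite reductase NiR were lower, each lost without any of 3 of the 6 libraries. By ZT18 GI, PRR37, PRR73 and FKF1 were still higher in LD, and the SD florigen pathway genes Hd3a and Ehd1 were detected in SD only. ZT14 gave 8457 genes (4291 up, 4166 down, and 11856 without the doubted libraries, 7974 shared). PRR95 rose by 5.91 (SE 0.84, adjusted p = 5.1e-07; 420 ± 29.5 CPM against 7.03 ± 5.83) and GI by 3.13 (SE 0.63, adjusted p = 0.000125, 2390 ± 558 CPM against 273 ± 56.9). PRR73 rose by 4.02, FKF1 by 3.56, PRR37 by 3.33 and TOC1 by 2.28. LHY also passed as higher (2.44), though its LD mean rests on replicate 1, a doubted library (175 ± 258 CPM against 32.2 ± 3.63) and the direction reversed without it (−0.28). Of the clock list 8 rose and 0 fell (8 adjusted over the list alone), and the list test passed (list adjusted p = 0.00017, 0.121). Where 2 adjusted p stand together for a list, here and below, the second is with an estimated correlation between its genes. Light harvesting genes rose in 12 of 14 (12 alone, list adjusted p = 1.88e-07, 0.584), with CAB1R up 6.40 (817 ± 325 CPM against 9.61 ± 7.87) and LHCA4 up 5.59; LHCA5 (−0.47) and LHCA6 (−0.59) did not pass. Light harvesting gave 11 up and 2 down and starch 7 up and 3 down without the doubted libraries. Starch genes rose in 7 of 11 (7 alone, list adjusted p = 0.00171, 0.633), among them GBSSII (5.78, 1060 ± 740 CPM against 19.4 ± 16.4), AGPL3 (4.82), SSI (3.87) and BEIIa (3.14, 288 ± 15.2 CPM against 32.6 ± 8.68). Flowering repressors gave 3 up and 1 down, led by Ghd7 (4.45, 1.63 ± 0.301 CPM against 0.0746 ± 0.0405). Flowering activators gave 4 up and 2 down (7 alone), with MADS51 (0.92) and MADS50 (0.52) up and MADS14 (−3.42) and Ehd2 (−0.88) down; their median was −0.41 while the list test pointed up. Evening complex genes gave 1 fall (ELF3-1, −0.82), photoreceptors 5 falls (PHYB −0.99, PIL14 −0.97, CRY1b −0.84), chlorophyll 2 falls (CHLD −1.26) and nitrogen 2 falls (NiR −2.53, GS2 −0.81). Cell wall genes gave 4 falls (5 alone, EXPA4 −2.53, EXPB4 −1.93, list adjusted p = 0.0297, 0.845). Gibberellin genes gave 4 up and 3 down (GA2ox6 4.28, KO2 −1.31, GA20ox1 −1.30), defence 3 up (PR1a 2.96), cold and drought 2 down (RAB16A −4.32), heat shock 3 up (HSP101 1.89), reference 1 up (ACT1 0.86), and root and dividing cell genes 0. Of the 56 named genes at ZT14, 36 stayed past the threshold without each library in turn; the most lost, 13, went without SD replicate 3.

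At ZT18 LD against SD gave 3596 genes (1532 up, 2064 down, and 10211 without the doubted libraries, which sit at other times, 3596 shared). GI rose by 3.72 (SE 0.66, adjusted p = 0.000179; 157 ± 4.76 CPM against 11.9 ± 0.271), PRR37 by 3.22 (16.5 ± 1.58 CPM against 1.76 ± 0.555), PRR73 by 3.98 and FKF1 by 3.37, while ZTL2 fell by 0.24; the clock list gave 4 up and 1 down (7 alone). Hd3a stood at 0 in LD and 1.55 ± 0.389 in SD, and its activator Ehd1 (Os10g0463400) at 0 and 2.89 ± 0.107, 2 of the 3 activators called lower. Nitrogen genes gave 2 falls (NiR −3.14, 132 ± 33.7 CPM against 1160 ± 15.1; NIA1 −2.53), chlorophyll genes 3 falls (HEMA1 −1.37, list adjusted p = 0.00696, 0.857), light harvesting genes 2 falls (LHCA3 −2.34, list adjusted p = 0.0138, 0.878) and defence genes 1 rise (MAS 4.54, list adjusted p = 0.0321, 0.878). Starch and cell wall genes gave 1 fall each (7 up and 3 down, and 1 fall, without the doubted libraries). Light harvesting genes gave 8 falls in that fit (list adjusted p = 0.000959, 0.627), chlorophyll genes 8 falls (2.3e-05, 0.324), activators 1 up and 6 down (0.0464, 0.488), nitrogen genes 3 falls (0.000111, 0.0513), defence genes 4 rises and clock genes 5 up and 3 down. Without LD replicate 1, 2 or 3 the ZT18 count was 2377, 2226 and 1494, and without SD replicate 1 or 2 it was 1810 and 1970.

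The other times gave fewer genes, and with only the compared groups in the fit ZT24, ZT2 and ZT10 gave 0 and ZT6 gave 1 (limma 1582 and 1613 at ZT24, 73 and 213 at ZT2, 420 and 281 at ZT10). ZT24 gave 2168 (764 up, 1404 down, and 9763 without the doubted libraries, 2097 shared). PRR37 (3.82), PRR73 (5.22) and GI (4.09) were called higher in LD there, and without the doubted libraries the same genes stood at −0.59, −3.36 and 0.42, so these calls rest on doubted libraries. ZT24 fell to 1088 without LD replicate 3, 410 and 260 without SD replicate 1 or 2, and rose to 5914 without SD replicate 3. ZT2 gave 772 (48 up, 724 down, and 8636 without the doubted libraries, 771 shared), among them the chlorophyll genes PORB (−1.65) and CHLI (−1.30, list adjusted p = 0.00953, 0.857). Its count was 0 without LD replicate 1 or 2, 266 without LD replicate 3, 0 without SD replicate 1 or 2, and 4011 without SD replicate 3. ZT10 gave 411 (86 up, 325 down, and 4810 without the doubted libraries, 396 shared), with COL4 up 1.91 and DREB1C down (−3.88; cold and drought list adjusted p = 0.000498, 0.352). That list gave 4 falls without the doubted libraries (list adjusted p = 1.48e-06, 0.00979). It fell to 9 without LD replicate 1 and to 32 and 75 without SD replicate 2 or 3, and rose to 1030 without SD replicate 1. ZT6 gave 0 by edgeR (unadjusted p below 0.05: 4711 genes; DESeq2 746; limma 0, and 5717 without the doubted libraries), 1002 without LD replicate 1 and 9 without SD replicate 1. List tests at these times were each lost with an estimated correlation: at ZT6 chlorophyll lower (adjusted p = 2.92e-05, 0.576), light harvesting lower (adjusted p = 0.00578, 0.878) and defence higher (adjusted p = 0.0213, 0.868), at ZT2 defence higher (adjusted p = 0.000406, 0.768) and cell wall lower (adjusted p = 0.0108, 0.768), at ZT10 photoreceptors higher (adjusted p = 0.031, 0.73) and at ZT24 starch higher (adjusted p = 0.0268, 0.856). In the fit without the doubted libraries, photoreceptors at ZT10 (list adjusted p = 0.16), cell wall at ZT14 (list adjusted p = 0.0501) and defence at ZT18 (list adjusted p = 0.0788) no longer passed as lists. Others newly passed there. At ZT24 these were photoreceptors (11 down, list adjusted p = 3.39e-05, 0.114), light harvesting (2 up and 11 down, 0.000102, 0.522), nitrogen (2 down, 0.00222, 0.14), cold and drought (5 down, 0.00595, 0.152) and activators (5 down, 0.0241, 0.452). At ZT2 they were starch (7 up, list adjusted p = 0.00143, 0.227) and light harvesting (4 down, 0.0357, 0.773), and at ZT14 nitrogen (3 down, 0.00185, 0.137) and chlorophyll (5 down, 0.0117, 0.579). Nitrogen also passed at ZT6 (3 down, list adjusted p = 0.00595, 0.169) and ZT10 (2 down, 0.00595, 0.169). Single list genes also passed at ZT24 (2 photoreceptor genes and 1 cold and drought gene lower, 2 defence genes and 1 heat shock gene higher), ZT10 (1 chlorophyll gene higher) and ZT2 (1 dividing cell and 1 reference gene lower). Over all times day length changed 12236 genes (19261 without the doubted libraries, 12053 shared).

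The elf3-1 elf3-2 mutant against WT at ZT18 asks what the loss of ELF3, which holds evening transcription down, does in the dark, and no library there was doubted. Clock genes that WT lowers after dusk, PRR37, PRR73, PRR95 and GI, were higher than WT in the mutant at night in LD and SD. Antenna genes such as CAB1R and LHCB2, which WT keeps near silent in the dark, were high as well. The flowering repressor Ghd7 and the blue light receptor CRY2 rose in LD and SD. With all libraries in the fit, the florigen gene Hd3a did not pass. SD gave 157 genes (133 up, 24 down, and 2713 without the doubted libraries, 155 shared) and LD 177 (154 up, 23 down; 4008, 177 shared). GI rose in SD by 6.65 (SE 0.75, adjusted p = 1.61e-07; 1200 ± 637 CPM against 11.9 ± 0.271) and in LD by 2.97 (SE 0.63, adjusted p = 0.0113, 1230 ± 567 CPM against 157 ± 4.76). PRR73 rose by 8.38 in SD (SE 1.23, 400 ± 211 CPM against 1.18 ± 0.395) and 3.87 in LD (SE 0.95, 278 ± 138 CPM against 19 ± 0.723). PRR37 rose by 6.53 (SE 0.81, 163 ± 90.6 CPM against 1.76 ± 0.555) and 2.88 (SE 0.66, 122 ± 57.2 CPM against 16.5 ± 1.58), PRR95 by 4.23 and 3.37, and TOC1 by 1.98 in SD alone. The clock list gave 5 up and 0 down in SD (7 alone, list adjusted p = 1.54e-12, 0.000606) and 4 up and 0 down in LD (6 alone, list adjusted p = 2.92e-05, 0.0622). Light harvesting genes rose in 8 of 14 in SD (11 alone, list adjusted p = 2.99e-29, 0.00833) and 9 of 14 in LD (11 alone, list adjusted p = 3.54e-23, 0.0248), with CAB1R up 6.52 in SD (526 ± 230 CPM against 5.72 ± 0.823) and 5.61 in LD (290 ± 130 CPM against 5.96 ± 1.16). Ghd7 was the only flowering repressor to pass, up 6.37 in SD (SE 1.25, adjusted p = 0.00201, 1.75 ± 1.08 CPM against 0.0197 ± 0.0341) and 4.45 in LD (SE 1.1, adjusted p = 0.0348, 1.27 ± 0.963 CPM against 0.0483 ± 0.0495). The repressor list passed in SD (4 alone, list adjusted p = 8.65e-05, 0.00142). Photoreceptors gave 2 rises in SD (CRY2 1.60, PIL12 1.90, list adjusted p = 0.0123, 0.576) and 1 in LD (CRY2 1.15), and ELF3-1 was the 1 evening complex gene to fall. In LD the diterpenoid gene CYP99A3 rose by 2.18 and the defence list passed (higher, 5 alone, list adjusted p = 0.003, 0.845). Flowering activators, chlorophyll, starch, gibberellin, cell wall, nitrogen, cold and drought, heat shock, root, dividing cell and reference genes gave 0. Without the doubted libraries, which sit at other times, flowering activators in SD gave 1 up and 5 down (list adjusted p = 0.0108, 0.434). Among them Hd3a (−2.61, 0.256 ± 0.231 CPM against 1.55 ± 0.389), Ehd1 (−1.90, 0.826 ± 0.77 CPM against 2.89 ± 0.107), MADS14 (−2.63) and MADS18 (−0.97) were lower and MADS51 (0.43) higher. In LD 1 activator passed (Ehd4 0.24). In that fit chlorophyll gave 2 in SD and 4 in LD, starch 1 and 3, gibberellin 3 and 1, cell wall 2 and 1, nitrogen 1 and 2, cold and drought 0 and 2, root 1 and 0 and dividing cell genes 0 and 1. Leaving out any 1 of the compared libraries lowered these counts, to at most 128 in SD and 138 in LD. The 6 compared libraries fitted alone gave more, 1299 in SD and 2162 in LD. The SD count was 70 without mutant replicate 2 and 75, 65 and 78 without WT replicate 1, 2 or 3. The LD count was 21 and 108 without mutant replicate 1 or 2 and 25, 28 and 25 without WT replicate 1, 2 or 3. Of 17 named genes in SD, 9 stayed past without each library (PRR37, PRR73, PRR95, GI, CRY2, CAB1R, LHCB2, LHCB5 and LHCA4). Of 16 in LD, 4 did (CAB1R, LHCB2, LHCA3 and LHCA4).

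Averaged over ZT6, ZT14 and ZT18 in LD and SD, the elf3-1 elf3-2 libraries were compared with WT over all conditions at once. The afternoon and evening clock genes GI, PRR37, PRR73, PRR95, TOC1 and FKF1 and the clock gene LUX itself were higher. Flowering repressors Ghd7, Hd1 and COL4 were higher, as were 10 of 14 light harvesting genes. Of these, LUX, FKF1, Hd1 and COL4 did not pass at ZT18. The average gave 3729 genes (2468 up, 1261 down, and 8110 without the doubted libraries, 3363 shared). LUX rose by 2.36 (adjusted p = 2.93e-05), PRR73 by 2.79 (SE 0.38), GI by 2.30 (SE 0.25, adjusted p = 6.07e-09), PRR37 by 2.29 (SE 0.27, adjusted p = 1.91e-08), FKF1 by 2.17, PRR95 by 2.08, TOC1 by 1.37 and PRR59 by 0.84, and ZTL1 fell by 0.14. The clock list gave 7 up and 1 down (9 alone, list adjusted p = 1.46e-06, 0.0248). Evening complex genes gave 1 up and 1 down (3 alone, median 0.14, while the list test pointed down, adjusted p = 0.772). Among repressors 3 of 8 rose (5 alone, list adjusted p = 0.16): Ghd7 by 3.02 (SE 0.37, adjusted p = 1.91e-08), Hd1 by 0.90 (adjusted p = 0.00855) and COL4 by 0.66. Activators gave 2 up (MADS51 0.22, Ehd4 0.13) and 1 down (MADS18 −0.61). Light harvesting genes rose in 10 of 14 (12 alone, list adjusted p = 7.76e-15, 0.133), with CAB1R up 3.05, LHCB2 up 2.64 and LHCA4 up 2.50. Photoreceptors gave 2 up (PIL12 0.77, CRY2 0.49) and 4 down (PIL15 −1.36, PIL16 −1.36, CRY1a −0.33, CRY1b −0.19; PIL15 and PIL16 reversed without the doubted libraries). Single falls came from chlorophyll (PORA −2.29; −0.39 and not past without the doubted libraries), starch (AGPL2 −0.17), gibberellin (GA20ox1 −0.35) and nitrogen (GS2 −0.36). Chlorophyll gave 2 up and 3 down without the doubted libraries, starch 3 and 4, gibberellin 3 and 3, nitrogen 1 and 1 and photoreceptors 4 and 5. Repressors gave 4 up and 1 down (list adjusted p = 0.022, 0.366) and cold and drought genes 5 up (list adjusted p = 0.0129, 0.169). Cold and drought genes gave 3 rises (DREB1B 2.43, lost without any of 11 libraries, DREB1A 1.99, without any of 3, SALT 1.18), defence 1 (WRKY45 0.91), root 1 rise (NRAMP5 0.43) and 1 fall (LSI1 −0.51), and cell wall, heat shock, dividing cell and reference genes 0 (1, 1, 0 and 0 without the doubted libraries). Leaving out 1 library kept the count between 2563 and 4235, and 28 of 37 named genes stayed past without each.

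At ZT6 and ZT14 single conditions hold doubted libraries. With only the compared groups in the fit ZT6 LD and ZT6 SD gave 0 genes, ZT14 SD 16 and ZT14 LD 18 (limma 100 and 123 at ZT6 LD, 58 and 94 at ZT6 SD, 182 and 194 at ZT14 SD). LUX and FKF1, which WT keeps low by day, were higher in the elf3-1 elf3-2 libraries at ZT6 LD, and LUX also at ZT6 SD. Mutant replicate 1 at ZT6 LD, a doubted library, lay nearest WT at ZT10 SD. At that time FKF1 (269 ± 57.2 CPM), LUX (59.3 ± 39.6), TOC1 (284 ± 63.2) and PRR59 (217 ± 21.2) had their highest WT means in SD. The clock gene rises at ZT6 LD may therefore come from that library, without which 2 genes passed. At ZT14 SD, already dark, PRR95, PRR37, GI and antenna genes were higher, as at ZT18. The DREB1 cold regulators were called at ZT6 LD only while the doubted libraries stayed in. ZT6 LD gave 774 genes (703 up, 71 down, and 1558 without the doubted libraries, 311 shared), with FKF1 up 4.65, LUX 4.44 (adjusted p = 0.0057), TOC1 2.23 and PRR59 1.26; DREB1B 7.66, DREB1A 6.99 and DREB1C 5.24 stood at 0.95, 1.14 and −0.73 and did not pass without the doubted libraries (cold and drought list adjusted p = 0.0481, 0.841). Its count was 2 without mutant replicate 1 and 2553 without replicate 3, and 455, 319 and 328 without WT replicate 1, 2 or 3. ZT6 SD gave 49 (44 up, 5 down, and 5615 without the doubted libraries, 49 shared), with LUX up 5.57 (adjusted p = 0.0451) and Hd1 up 3.63 (SE 0.73, adjusted p = 0.0136; 8 ± 5.37 CPM against 0.644 ± 0.174). That count was 487, 4 and 30 without mutant replicate 1, 2 or 3, and 5 and 1 without WT replicate 2 or 3. List tests lower at ZT6 SD were chlorophyll (adjusted p = 6.39e-06; 8 falls alone, and adjusted p = 0.522 with an estimated correlation), light harvesting (list adjusted p = 0.00171, 0.868) and photoreceptors (list adjusted p = 0.0106, 0.576). ZT14 SD gave 408 (326 up, 82 down, and 1649 without the doubted libraries, 248 shared): clock genes 6 up (7 alone, PRR95 4.64, PRR37 3.24, GI 2.89, list adjusted p = 1.73e-08, 0.00734), light harvesting genes 10 up (11 alone, LHCA4 6.06, CAB1R 5.74, list adjusted p = 2.19e-27, 0.0116) and starch genes 3 up (GBSSII 3.89, SSI 2.47, BEIIa 1.94; SSI and BEIIa 0.49 and 0.11 and not past without the doubted libraries). Flowering repressors gave 1 rise and gibberellin genes 1 fall (KO2 −0.97). This count was 71, 770 and 1238 without mutant replicate 1, 2 or 3 and 222, 103 and 104 without WT replicate 1, 2 or 3. ZT14 LD, with 2 mutant libraries, gave 0 by edgeR (unadjusted p below 0.05: 1470; DESeq2 26; limma 6 and 2, and 1182 without the doubted libraries); it gave 1 without mutant replicate 3 and 2 without WT replicate 1, and the cold and drought list tested higher (list adjusted p = 0.00171, 0.494). Of its 7 genes 4 were higher without the doubted libraries (list adjusted p = 3.99e-05, 0.0177). In that fit ZT14 LD also gave light harvesting higher (1 past, list adjusted p = 2.15e-05, 0.461) and evening complex genes lower (1 past, 0.0376, 0.153). At ZT6 LD cell wall tested higher (2 past, list adjusted p = 0.00156, 0.172) and photoreceptors lower (0 past, 0.0376, 0.452), while the cold and drought list still passed with 1 gene (0.0354, 0.302). ZT6 SD gave light harvesting 1 up and 10 down, photoreceptors 8 down, chlorophyll 7 down and activators 3 down (list adjusted p = 0.0399, 0.488).

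**Figure D3:**
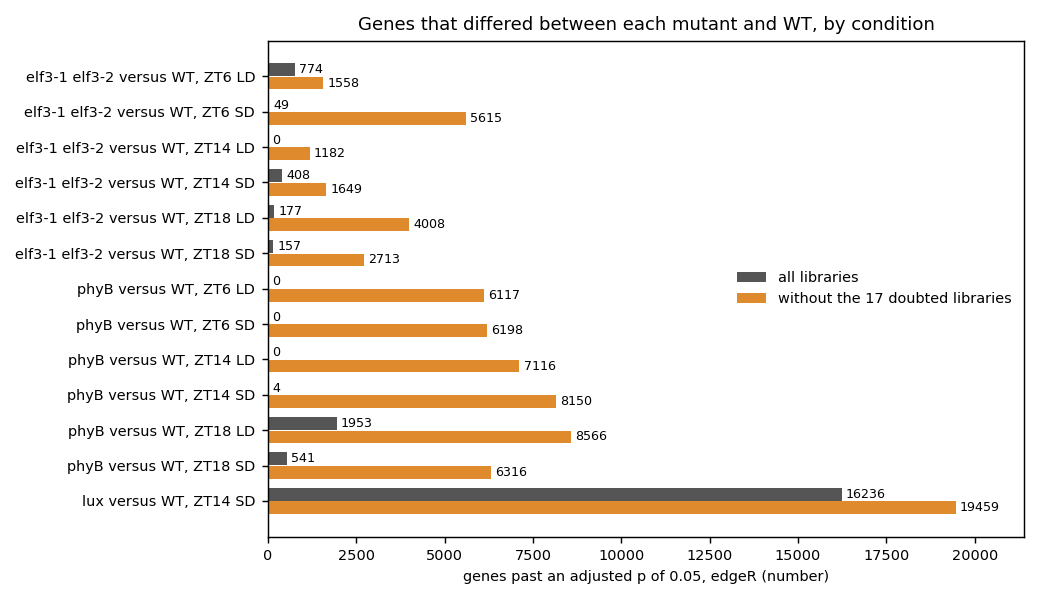
Number of genes past an adjusted p of 0.05 (edgeR) between each labelled mutant and WT in each condition. Grey bars use all libraries under their labels; orange bars leave out the 17 doubted libraries.

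The phyB mutant against WT at ZT18 asks what the red light receptor sets during the night, and no library there was doubted. Antenna gene CAB2R was higher in the mutant in LD and SD. Of the gibberellin synthesis genes, KO2 rose in LD and SD and GA20ox2, the semi-dwarf gene, in SD, where leaving out any 1 of the 6 libraries lost both. In LD the chlorophyll gene PORA, the starch gene AGPL3 and the clock gene PRR95 were higher, and the gibberellin breakdown gene GA2ox3 was lower. The late embryogenesis gene LEA3 fell in SD. LD gave 1953 genes (1119 up, 834 down, and 8566 without the doubted libraries, 1952 shared) and SD 541 (250 up, 291 down; 6316, 541 shared). CAB2R rose by 3.62 in LD (SE 0.55, adjusted p = 0.00025; 319 ± 12.5 CPM against 26.1 ± 3.51) and 2.82 in SD (SE 0.53, adjusted p = 0.0021, 427 ± 74.9 CPM against 60.4 ± 4.06). Light harvesting gave 2 rises in LD (4 alone, LHCA3 2.64, list adjusted p = 0.013, 0.878) and 1 in SD (list adjusted p = 0.0421, 0.878). In LD PORA rose by 4.83 (SE 1.36, 860 ± 115 CPM against 30.4 ± 8.65), the 1 chlorophyll gene to pass, and PRR95 by 3.59 (SE 0.78, 44 ± 2.19 CPM against 3.68 ± 0.741), the 1 clock gene. Starch genes gave 2 rises and 1 fall in LD (7 alone): AGPL3 2.96 (SE 0.72, 169 ± 11.1 CPM against 21.8 ± 2.89), AGPL2 0.48 and AGPL1 −0.81 (SE 0.18, 129 ± 3.87 CPM against 227 ± 19.3). Gibberellin genes gave 1 rise and 1 fall in LD (3 alone, KO2 1.01; GA2ox3 −2.66, 0.556 ± 0.164 CPM against 3.52 ± 0.58) and 2 rises in SD (3 alone, GA20ox2 3.23, 28.8 ± 2.33 CPM against 3.07 ± 0.701; KO2 0.85), and their list passed in neither (adjusted p = 0.529 in LD and 0.819 in SD). In LD the repressor MADS56 rose (0.53) and the blue light receptor CRY1b fell (−0.44); in SD LEA3 fell (−5.57, 0.25 ± 0.141 CPM against 12 ± 4.75) and the root transporter NRAMP5 fell (−1.27). The defence list tested higher in SD with 0 members past (3 alone, list adjusted p = 0.00517, 0.857). Evening complex genes and flowering activators gave 0 in LD and SD, as did clock genes in SD. Without the doubted libraries, which sit at other times, evening complex genes again gave 0 and activators gave 5 rises in SD (list adjusted p = 0.00304, 0.324). Among them were MADS14 (2.59), MADS15 (near 0, 0.286 ± 0.12 CPM against 0.0295 ± 0.0511), MADS18 (1.1) and Ehd1 (1.01). In LD Ehd1 (0.506 ± 0.0465 CPM against 0) and MADS18 (1.32) rose. Clock genes gave 2 up and 2 down in SD and 6 up and 2 down in LD (list adjusted p = 0.00395, 0.434). In that fit light harvesting gave 9 up and 2 down in LD (list adjusted p = 0.00314, 0.669) and 5 up in SD (0.0144, 0.746), and starch 7 up and 3 down in LD (0.0261, 0.434) and 5 up and 3 down in SD. Gibberellin genes gave 4 up and 2 down in LD and 3 up and 3 down in SD, chlorophyll genes 4 up and 3 up, photoreceptors 4 up and 4 down and 5 up and 4 down. Repressors gave 4 up in LD (list adjusted p = 0.0501) and 2 up and 1 down in SD, defence genes 1 up and 4 up (0.0208, 0.685), and nitrogen genes 1 up and 2 down in LD and 2 down in SD (0.0134, 0.245). The LD count was 681, 501 and 621 without mutant replicate 1, 2 or 3 and 891, 467 and 541 without WT replicate 1, 2 or 3. In the same order the SD count was 127, 126 and 169, and 122, 140 and 150. Of 15 named genes in LD, 3 stayed past without each library (PRR95, CAB2R and AGPL1), and of 9 in SD, 1 did (CAB2R).

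Averaged over the 6 conditions 7 of 14 light harvesting genes were higher in the phyB libraries. Among gibberellin genes GA20ox2 and the breakdown gene GA2ox6 rose and the breakdown gene GA2ox3 fell, and the list test did not pass (adjusted p = 0.548). The phytochrome-interacting factor genes PIL15 and PIL16 and the starch gene AGPL3 were higher, though PIL16 was lost without any of 12 of the libraries. Evening complex genes did not pass (2 fell without the doubted libraries). The average gave 4025 genes (2414 up, 1611 down, and 13452 without the doubted libraries, 3961 shared). Light harvesting genes rose in 7 of 14 (8 alone, CAB2R 1.24, SE 0.21, adjusted p = 0.000135; LHCB2 1.06, list adjusted p = 0.0101, 0.878), though CAB1R (1.00) and LHCA4 (0.98) stood at 0.34 and 0.10 and did not pass without the doubted libraries. Gibberellin genes gave 3 up and 1 down (5 alone): GA2ox6 1.59, GA20ox2 1.13, KO2 0.33 and GA2ox3 −1.34. Photoreceptors gave 2 up (PIL15 1.27, PIL16 1.18) and 3 down (PHYB −0.32, PIL14 −0.26, CRY1b −0.22). Starch genes gave 3 up and 2 down (AGPL3 1.19, AGPS1 0.85, BEI 0.31, AGPL1 −0.27, SUT1 −0.26), and the clock list 1 fall (ZTL2 −0.10; 4 alone). The activator MADS18 (0.68), the repressor MADS56 (0.22), PORA (1.60) and the expansin EXPA1 (0.99) were the only members of their lists to pass with all libraries. Without the doubted ones activators gave 4 up and 2 down, repressors 4 up and 1 down, chlorophyll 7 up (list adjusted p = 0.0133, 0.579) and cell wall 5 up (list adjusted p = 0.0399, 0.434). Clock genes gave 3 up and 4 down, photoreceptors 5 and 7, starch 6 and 2 (list adjusted p = 0.0125, 0.399) and gibberellin genes 7 and 3. Heat shock genes HSP101 (0.80) and HSP16.9A (0.78) and defence genes PR1a (1.21) and PBZ1 (0.74) rose, and nitrogen, cold and drought, root, dividing cell and reference genes gave 0 (2, 4, 2, 2 and 1 without the doubted libraries). Leaving out 1 library kept the count between 2941 and 5270, and 19 of 25 named genes stayed past without each.

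At ZT6 and ZT14 few or no genes passed for phyB while every library kept its label. LHCB5 and LHCA4 passed at ZT14 SD, and both stood lower than WT, without passing, once the doubted libraries were left out. By edgeR ZT6 LD gave 0 (unadjusted p below 0.05: 1015; DESeq2 20; limma 0, and 6117 without the doubted libraries), ZT6 SD 0 (1485; 37; 0; 6198) and ZT14 LD 0 (938; 10; 1 and 0; 7116). ZT14 SD gave 4 (4 up, 0 down, and 8150 without the doubted libraries, 2 shared), and 0 with only the compared groups in the fit (limma 43 and 17), with LHCA4 up 4.24 and LHCB5 up 3.71 (−0.82 and −0.53 without the doubted libraries). Without WT replicate 1 these counts were 1 at ZT6 LD, 14 at ZT6 SD, 17 at ZT14 LD and 1223 at ZT14 SD. Without phyB replicate 1 ZT6 SD gave 1 and ZT14 SD 87; ZT14 SD gave 10 and 7 without phyB replicate 2 or 3 and 0 and 0 without WT replicate 2 or 3. List tests here were each lost with an estimated correlation: cell wall higher at ZT6 LD (adjusted p = 7.36e-05, 0.322) and ZT14 LD (adjusted p = 0.0316, 0.845), chlorophyll higher at ZT6 LD (adjusted p = 0.0306, 0.878) and ZT14 LD (adjusted p = 0.00801, 0.857), defence lower at ZT14 LD (adjusted p = 0.0231, 0.868), and light harvesting (7 alone, adjusted p = 0.0142, 0.878) and defence (5 alone, adjusted p = 0.00107, 0.841) higher at ZT14 SD. Light harvesting at ZT14 SD gave, without the doubted libraries, 1 up and 4 down (median −0.51, list adjusted p = 0.535), and at ZT14 LD cell wall (list adjusted p = 0.0928) and defence (list adjusted p = 0.758) did not pass. Nitrogen genes then gave 3 falls at ZT14 SD (list adjusted p = 3.39e-05, 0.0404) but 3 rises at ZT14 LD (0.00143, 0.13) and at ZT6 LD (0.103). At ZT14 LD light harvesting gave 9 up (list adjusted p = 6.77e-06, 0.439), chlorophyll 8 up (9.94e-08, 0.153), starch 7 up (2.71e-06, 0.0513) and gibberellin 4 up and 2 down (0.0222, 0.302). At ZT6 LD chlorophyll gave 5 up (list adjusted p = 5.98e-05, 0.366), starch 7 up and 1 down (5.98e-05, 0.13), gibberellin 7 up and 2 down (0.00389, 0.153) and cell wall 6 up (0.00116, 0.164). Activators gave 4 up at ZT6 SD (list adjusted p = 0.0376, 0.472) and 5 up at ZT14 SD (0.0197, 0.434), cell wall 4 up at ZT6 SD (0.0425, 0.434), and defence 6 up at ZT14 SD (0.0141, 0.652).

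Whether a mutation acts differently in LD and SD was tested as an interaction over ZT6, ZT14 and ZT18. With all libraries clock and flowering genes did not pass for either mutant, though 6 clock and 9 light harvesting genes did for elf3-1 elf3-2 when adjusted over the list alone. Without the doubted libraries 8 of 10 clock genes and 12 of 14 light harvesting genes passed for elf3-1 elf3-2, and 5 clock genes and 9 of 10 chlorophyll genes for phyB, so this outcome depends on those libraries. Whether GI and PRR37 rise more in SD than LD at ZT18 was not tested by itself. For elf3-1 elf3-2 the count was 0 by edgeR (smallest adjusted p = 0.223; unadjusted p below 0.05: 2158; DESeq2 37; limma 0 and 2, and 1374 without the doubted libraries), and it was 12 and 66 without mutant ZT6 LD replicate 2 or 3. For phyB 4 genes passed (4547 without the doubted libraries, 4 shared; unadjusted p below 0.05: 686; DESeq2 6; limma 3 and 0), each with adjusted p = 0.0286 and none in a list. At ZT18 all 4 were lower in phyB than WT in LD and higher in SD. Os06g0230100 stood at 37.2 ± 0.605 CPM in phyB and 69.2 ± 6.42 in WT in LD, and 106 ± 3.23 and 58.1 ± 5.43 in SD. Os07g0526600 (0.636 ± 0.769, and 15 ± 7.59, in LD, 2.78 ± 2.39, and 0.0558 ± 0.0542, in SD), Os10g0515900 (0.484 ± 0.135, and 4.66 ± 0.673, 1.3 ± 1.23, and 0.254 ± 0.024) and Os11g0211800 (0.26 ± 0.0623, and 0.814 ± 0.352, 1.43 ± 0.681, and 0.133 ± 0.121) were low. Of these 4, 0 stayed past without phyB ZT18 LD replicate 1 or 2, phyB ZT18 SD replicate 2 or 3, WT ZT6 LD replicate 3, WT ZT6 SD replicate 2 or 3, WT ZT18 LD replicate 2 or 3, or any WT ZT18 SD replicate. The count was 2 without phyB ZT6 SD replicate 3, 1 without phyB ZT18 LD replicate 3 and 11 without WT ZT14 LD replicate 1.

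The lux mutant against WT at ZT14 SD asks what the DNA-binding member of the Evening Complex holds down after dusk. As in elf3-1 elf3-2, the clock genes PRR37, PRR73, PRR95 and GI, the repressor Ghd7 and 8 of 14 light harvesting genes were higher than in WT. Beyond that, root genes such as the silicon transporter LSI1 and the root marker RCc3, and dividing cell genes such as the cyclin CYCB1;1 and the meristem gene OSH1, were higher in all 3 libraries than in any other library of the series. Of 10 chlorophyll genes 6 fell, as did 3 of 4 nitrogen genes; neither list test passed with all libraries (adjusted p = 0.08 and 0.562). Both passed without the doubted ones (adjusted p = 0.0133 and 0.0402; 0.579 and 0.38 with an estimated correlation). The label gives the same whole plant source for these libraries as for all others. The comparison gave 16236 genes (9424 up, 6812 down, and 19459 without the doubted libraries, 15849 shared; median log2 fold change of all genes 0.105). Clock genes gave 6 up and 2 down (8 alone, PRR73 3.63, PRR95 2.85, PRR37 2.75, 132 ± 6.56 CPM against 19.6 ± 1.44; GI 2.45, 1490 ± 64.9 CPM against 273 ± 56.9; TOC1 1.14; PRR59 0.95; ZTL1 −0.77; ZTL2 −0.50, list adjusted p = 0.857). Evening complex genes gave 3 falls (ELF3-1, ELF3-2 and ELF4a, −0.87). Repressors gave 2 up and 4 down (7 alone, Ghd7 3.02, 0.609 ± 0.0335 CPM against 0.0746 ± 0.0405; COL4 1.54; MADS56 −1.12; DTH8 −0.87), and activators 3 up and 1 down (Ehd3 0.48, MADS51 0.47); Ehd1 was at 0 in lux and 1.36 ± 1.84 in WT. Light harvesting genes gave 8 up and 2 down (CAB1R 5.21, 360 ± 40.3 CPM against 9.61 ± 7.87; LHCB5 4.71; LHCA6 −2.09; LHCA5 −1.94, list adjusted p = 0.334), photoreceptors 1 up and 5 down (CRY2 1.16, CRY1a −1.76, CRY1b −1.45) and chlorophyll 6 down (CHLI −1.72, CHLD −1.69). Root genes rose in 6 of 6 (list adjusted p = 1.43e-07, 3.34e-05), with LSI1 at 325 ± 54.8 in lux and at most 24.2 in the other 71 libraries, LSI2 at 290 ± 55 and at most 0.389, and NRAMP5 at 96.3 ± 12.1 and at most 16.3. RCc3 stood at 80.1 ± 7.75 and 0, and AMT1;2 at 42.5 ± 17.8 and at most 0.151. IRT1 stood at 12.9 ± 1.99 and at most 4.62. Dividing cell genes rose in 6 of 6 (list adjusted p = 0.000317, 0.1), with PCNA at 41.9 ± 5.55 and at most 21.1, CDKB2;1 at 24.7 ± 3.08 and at most 1.81, CYCB1;1 at 20.8 ± 2.16 and at most 1.85, and CYCB2;2 at 14.9 ± 1.01 and at most 0.98. OSH15 stood at 9.81 ± 0.856 and at most 0.347, and OSH1 at 9 ± 1.65 and at most 0.0754. Nitrogen genes gave 1 up and 3 down (NRT2.1 7.13, 11.8 ± 2.58 CPM against 0.0893 ± 0.11; NiR −4.24, 56.1 ± 2.7 CPM against 1060 ± 667; NIA1 −2.17; GS2 −2.13). Starch gave 4 up and 5 down (AGPL3 4.95, GBSSII 3.39, AGPL1 −1.63), gibberellin 3 up and 3 down (GA3ox2 4.31, GA2ox1 3.34), and cell wall 4 up (5 alone, EXPA1 3.39, EXPB4 2.62). Defence genes gave 4 up and 2 down (7 alone, PR1a 4.79, PR1b −4.53, WRKY45 −1.48), cold and drought 3 up and 1 down (DREB1A 3.27, RAB16A −3.31), heat shock 0 and reference 2 up (ACT1 2.33, 275 ± 10.1 CPM against 54.6 ± 3.29). Light harvesting gave 11 up and 2 down in the fit without the doubted libraries (list adjusted p = 0.0404, 0.773), photoreceptors 4 up and 8 down, chlorophyll 7 down, clock genes 8 up and 2 down and evening complex genes 4 down. Root genes (list adjusted p = 9.77e-05, 0.00979) and dividing cell genes (list adjusted p = 0.00222, 0.153) again rose in 6 of 6. Leaving out 1 library kept the count between 14588 and 15716, and 57 of 71 named genes stayed past without each.

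**Figure D4:**
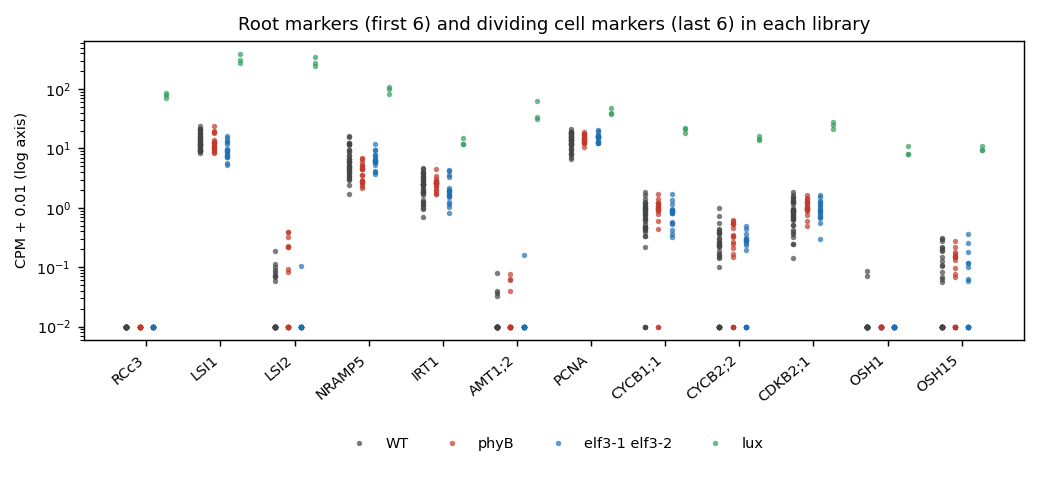
Root markers (RCc3 to AMT1;2) and dividing cell markers (PCNA to OSH15) in all 74 libraries, coloured by labelled genotype. Each point is 1 library and the vertical axis is CPM plus 0.01 on a log scale.

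The lux mutant against elf3-1 elf3-2 at ZT14 SD asks whether loss of LUX and loss of ELF3 act alike. Root and dividing cell genes rose in 6 of 6 each, as they did against WT. The clock genes PRR37, PRR73 and GI, higher than WT in lux, did not pass against elf3-1 elf3-2. LUX transcript was lower in lux than in the double mutant. The comparison gave 14995 genes (8599 up, 6396 down, and 18626 without the doubted libraries, 14468 shared). Root genes passed as a list (list adjusted p = 2.97e-08, 2.45e-05), as did dividing cell genes (list adjusted p = 0.000104, 0.0622). Clock genes gave 0 up and 4 down (4 alone, ZTL1 −0.68, ZTL2 −0.47, FKF1 −1.89, and PRR95 −1.79, which reversed to 0.43 without elf3-1 elf3-2 replicate 1), evening complex genes 2 down (LUX −1.92, adjusted p = 0.0457; ELF4a −0.59), photoreceptors 5 down (CRY1b −1.18, PHYB −0.76), light harvesting 5 down (list adjusted p = 0.0595), chlorophyll 6 down (7 alone), repressors 2 down (MADS56 −1.18) and activators 2 up and 1 down. Starch gave 2 up and 6 down, gibberellin 3 up and 2 down, cell wall 5 up, nitrogen 1 up and 3 down (NRT2.1 6.96, NiR −3.77), defence 2 up and 2 down, cold and drought 3 up, heat shock 0 and reference 2 up. Without the doubted libraries light harvesting gave 10 down (list adjusted p = 0.00314, 0.669), chlorophyll 9 down (0.000778, 0.434), photoreceptors 2 up and 10 down (0.0206, 0.434) and nitrogen 1 up and 3 down (0.0371, 0.366). Evening complex genes gave 4 down, repressors 5 down and clock genes 2 down. Leaving out 1 library kept the count between 13681 and 14491, and 45 of 60 named genes stayed past without each.

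Effects against WT were compared across genes, which are not independent replicates. For lux and elf3-1 elf3-2 at ZT14 SD the correlation was 0.301 (jackknife SE 0.137, 9 libraries). The mutants share their WT controls, and counts simulated without any effect gave a higher correlation (mean 0.516, highest 0.529) and a lower covariance (0.375 against 0.747 observed). Simulated counts hold no effects, so the correlations cannot be set against each other. The covariance difference was 0.372. It is no estimate of a shared mutant effect, since the simulated counts hold no doubted libraries. Among the real ones, replicate 1 of WT at ZT14 SD, a control of both effects, lay at 1 on the phyB markers. Replicate 1 of elf3-1 elf3-2 lay at 0.11 on its own markers. Genes past the threshold in lux and in elf3-1 elf3-2 numbered 181 higher in both (106 if independent), 66 lower in both (19.3 if independent) and 22 opposite. For phyB and elf3-1 elf3-2 the average effects had a correlation of 0.154 (jackknife SE 0.235, 53 libraries; 0.495 simulated), which changed sign over genes of at least 10 CPM (−0.015) and on log2(TPM + 1) (−0.116) and fell to 0.044 without phyB ZT6 SD replicate 1, and a covariance of 0.053 against 0.063 simulated (difference −0.009), with 238 higher in both (206 if independent), 112 lower in both (70.3 if independent) and 168 opposite. The WT controls were not split into separate sets for each mutant, so part of these overlaps may come from the shared controls.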

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

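The tests of replicate labels, of thinned marker positions, of a batch of replicate 1, of tissue markers and of neighbouring genes were chosen after the results were seen; those of library totals, of thinning lux, of a lux batch and of other splits were planned. The effect of phyB differed between LD and SD in 4 genes by the interaction test, a difference between groups. All 4 were lower than WT at ZT18 in LD and higher in SD, and none was named before the data were examined. Among the 30 splits of the samples, 12 gave as many genes (4 in the real split, 5052 in the highest other), so chance is not excluded.

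Replicate 1 of WT, phyB and elf3-1 elf3-2 at ZT6 and ZT14 stood apart from replicates 2 and 3. Their totals go with depth as a cause: 1 of the 11 libraries had a larger total than the mean of the others of its group and 10 a smaller one, as depth predicted. Thinning argues against it: after 33 libraries were thinned to 28.7 M counts 11 of 11 kept the markers of another genotype, with no position moving by more than 0.03. A shared batch is argued against: on phyB markers replicate 1 labelled WT lay at 0.99 to 1, phyB at 0. Between genotypes of a condition, deviations from replicates 2 and 3 had mean correlation −0.251. Of 10 pairs 7 lay below 0 (range −0.61 to 0.06), but pairs share libraries. A mislabelled sample stays open: 11 of 11 libraries carried markers of another genotype, against 0 of the other 42 outside ZT18 and lux, with the labels WT, phyB and elf3-1 elf3-2 sitting on phyB, elf3-1 elf3-2 and WT profiles. Those labelled WT and phyB lay nearest phyB and elf3-1 elf3-2 of their own condition. The 3 labelled elf3-1 elf3-2 lay nearest WT of another condition (ZT10 SD for ZT6 LD, ZT6 LD for ZT6 SD, ZT14 LD for ZT14 SD). An exchange of genotype labels within a condition leaves these 3 unexplained. In the deposited order, lux aside, each of the 11 lay nearest the group of the next column, as a shift of labels by a column would give. Replicate 1 of WT at ZT10 SD also lay nearest the next, ZT10 LD. That at ZT10 LD lay nearest WT at ZT6 SD, where the run begins. Replicate 3 of WT went the same way: ZT24 SD to ZT24 LD, ZT24 LD to ZT2 SD and ZT2 SD to ZT2 LD. This order was read after the distances were seen. The 5 WT libraries at ZT10, ZT2 SD and ZT24 were picked on such distances, and replicate 3 at ZT2 LD, also doubted, lay nearer its own group. The distances therefore do not test a wrong label and leave it open. No biological explanation was tested, and the values cannot show which record of a sample is right.

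Far more genes differed between lux and WT at ZT14 SD than in the other comparisons of a mutant with WT. Depth is argued against: after thinning the 6 libraries to 29.7 M counts, 16123 genes passed. Another tissue in the lux libraries stays open: 12 of 12 root and dividing cell markers, listed before the data were examined, were higher in every lux library than in all 71 others, from LSI1 and LSI2 among the most abundant to OSH1 among the least. Of these markers 3 root and 3 dividing cell genes also reach 1 CPM in some other library. RCc3 stood at 0 in all 71 others, and LSI2, AMT1;2, OSH1 and OSH15 had a median of 0 CPM there. A larger share of roots and dividing tissue is a candidate explanation, and so is tissue that the other libraries lacked. A library batch cannot be told apart from genotype, since all lux libraries and no others would share it; 6608 genes had every lux library outside the range of the others (5196 above, 1412 below). The loss of LUX, the biological difference that the labels name, stays open and untested apart from these.

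Genes that differed between phyB and WT at ZT18 in LD and SD lay beside each other on the chromosomes: a share of 0.275 (74 of 269) had another within 5 genes on either side, against at most 0.164 in 100 random draws (median 0.0892). For elf3-1 elf3-2 the share was 0.1 (6 of 60), against at most 0.133. Linkage to the PHYB locus on chromosome 3 is argued against as the whole cause, since a share of 0.0541 (4 genes) of those with a neighbour lay there. A strain variant against the reference stays open and may account for part of the phyB calls: 33 of the 45 genes called on chromosome 11 had a neighbour, and chromosome 11 held 16.7% of called genes against 6.06% of tested ones. Os11g0605100 and Os11g0606400, chosen after their values were seen, stood at 0 CPM in WT at ZT18 and at 167 ± 18.4 and 71.9 ± 4.72 in phyB in LD (mean ± standard deviation, n = 3). The loss of PHYB itself stays open as well.

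Other splits of the samples were counted for each comparison, with the real split included. With 30 splits, 1 split, the real one, gave as many genes for the averages of elf3-1 elf3-2 (3729, highest other 161) and phyB (4025, highest other 1694). The same held for WT LD against SD over all times (12236, highest other 4280) and time of day in LD (16290, highest other 9393) and SD (20372, highest other 13976). That share is under 0.05, the smallest that 30 splits can give, and argues against chance without excluding it. The other splits also mix libraries whose labels are doubted. Where the real count is 0 every split gives as many, so the splits test nothing there: this holds for the elf3-1 elf3-2 interaction (30 of 30, real 0, highest other 1792) and the counts of 0 below. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes came from 1 split at elf3-1 elf3-2 ZT14 SD (408, highest other 134), ZT18 LD (177, highest other 1) and ZT18 SD (157, highest other 0), and at phyB ZT18 LD (1953, highest other 1) and ZT18 SD (541, highest other 6). The same held for lux over WT (16236, highest other 17) and over elf3-1 elf3-2 (14995, highest other 1516), and for WT LD against SD at ZT10 (411, highest other 50), ZT14 (8457, highest other 173) and ZT18 (3596, highest other 1). As many came from 2 splits at elf3-1 elf3-2 ZT6 LD (774, highest other 1857), 3 at ZT6 SD (49, highest other 354), 2 at WT ZT2 (772, highest other 775), 4 at WT ZT24 (2168, highest other 3942) and 10 at WT ZT6 (0, highest other 25). For phyB 10 did at ZT6 LD (0, highest other 2953), 10 at ZT6 SD (0, highest other 2446), 10 at ZT14 LD (0, highest other 2690) and 4 at ZT14 SD (4, highest other 2712). Splits that call several times the real count point to a structure of the samples; the highest for phyB put its replicate 1 with replicates 2 and 3 of WT.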

How the results depend on the processing

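The tests that left out the 17 doubted libraries, left out ZT24, ran estimateDisp first or left out single libraries in the list and correlation results were chosen after the data were seen; the others were planned. Counts are called changed beyond 1.5 times. RLE size factors (28 results), a filter of at least 1 CPM in at least 3 libraries (27) and leaving out ZT24 (3) changed none. Over all named genes and settings 12349 values kept direction and side of the threshold, 616 no longer passed, 269 newly passed and 11 reversed. Depth limits genes near 0 CPM, where a library needs 3 counts to be told from 0. Here elf3 stands for elf3-1 elf3-2, day length for WT LD against SD. Below, each value stands before the reported count it replaces. Unless stated, the cause was not tested.

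DESeq2 raised 15 of 27 counts: elf3 1278 for 774 at ZT6 LD, 337 for 49 at ZT6 SD, 26 for 0 at ZT14 LD, 796 for 408 at ZT14 SD, 278 for 177 at ZT18 LD, 268 for 157 at ZT18 SD, 37 for 0 for the interaction. For phyB it gave 20 for 0 at ZT6 LD, 37 for 0 at ZT6 SD, 10 for 0 at ZT14 LD, 63 for 4 at ZT14 SD, 974 for 541 at ZT18 SD. For day length it gave 1441 for 772 at ZT2, 746 for 0 at ZT6, 623 for 411 at ZT10. Without a filter beyond 1 count 1 of 27 changed: elf3 28 for 49 at ZT6 SD. A replicate block changed 1 of 30: elf3 90 for 49 at ZT6 SD. Running estimateDisp before the fit lowered 7 of 27: elf3 32 for 49 at ZT6 SD, 69 for 177 at ZT18 LD. For phyB it gave 1 for 4 at ZT14 SD, 1227 for 1953 at ZT18 LD, 309 for 541 at ZT18 SD, 0 for 4 for the interaction. For day length it gave 240 for 411 at ZT10.

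Fitting the compared groups alone changed 16 of 27: elf3 0 for 774 at ZT6 LD, 0 for 49 at ZT6 SD, 18 for 0 at ZT14 LD, 16 for 408 at ZT14 SD, 2162 for 177 at ZT18 LD, 1299 for 157 at ZT18 SD, 17 for 0 for the interaction. For phyB it gave 0 for 4 at ZT14 SD, 8495 for 1953 at ZT18 LD, 6787 for 541 at ZT18 SD, 0 for 4 for the interaction. For day length it gave 0 for 772 at ZT2, 1 for 0 at ZT6, 0 for 411 at ZT10, 9880 for 3596 at ZT18, 0 for 2168 at ZT24. Such a fit has fewer residual degrees of freedom, and at ZT18 its variance holds no doubted library. With limma-trend on log2(TPM + 1) 7 of 29 changed: elf3 100 for 774 at ZT6 LD, 6 for 0 at ZT14 LD, 182 for 408 at ZT14 SD. For phyB it gave 1 for 0 at ZT14 LD, 43 for 4 at ZT14 SD. For day length it gave 73 for 772 at ZT2. With log2(TPM + 0.1) 8 of 27 changed: elf3 123 for 774 at ZT6 LD, 94 for 49 at ZT6 SD, 2 for 0 at ZT14 LD, 194 for 408 at ZT14 SD, 2 for 0 for the interaction. For phyB it gave 17 for 4 at ZT14 SD, 0 for 4 for the interaction. For day length it gave 213 for 772 at ZT2.

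Leaving out the 17 doubted libraries raised 23 of 30 results: elf3 8110 for 3729 for the average, 1558 for 774 at ZT6 LD, 5615 for 49 at ZT6 SD, 1182 for 0 at ZT14 LD, 1649 for 408 at ZT14 SD, 4008 for 177 at ZT18 LD, 2713 for 157 at ZT18 SD, 1374 for 0 for the interaction. For phyB it gave 13452 for 4025 for the average, 6117 for 0 at ZT6 LD, 6198 for 0 at ZT6 SD, 7116 for 0 at ZT14 LD, 8150 for 4 at ZT14 SD, 8566 for 1953 at ZT18 LD, 6316 for 541 at ZT18 SD, 4547 for 4 for the interaction. For day length it gave 19261 for 12236 over all times, 8636 for 772 at ZT2, 5717 for 0 at ZT6, 4810 for 411 at ZT10, 10211 for 3596 at ZT18, 9763 for 2168 at ZT24. The ZT18 groups lost no library. RLE factors and other filters changed no ZT18 count, and fitting the compared groups alone raised each. That points to the variance, not tested alone. List tests past the threshold went from 47 to 86 without the doubted libraries and to 9 with an estimated inter-gene correlation. Among the named results, without the doubted libraries PIL15 (0.14) and PIL16 (0.20) reversed in the elf3 average, PRR37 (−0.34), PRR73 (−0.35) and Hd1 (−0.38) in the phyB average, LHY (−0.21) in day length at ZT14, and PRR95 (0.39) and BEIIa (0.21) in lux over elf3. Calls of list genes outside these rows also changed sign: PRR37 (−0.59) and PRR73 (−3.36) in day length at ZT24, LHCA4 (−0.82) and LHCB5 (−0.53) in phyB at ZT14 SD and DREB1C (−0.73) in elf3 at ZT6 LD are among them. Single libraries did the same: without 1 library LHY ranged from −0.28 (WT ZT14 LD replicate 1) to 2.92 (replicate 2), PRR95, lux versus elf3-1 elf3-2, ZT14 SD, from −2.31 (elf3 ZT14 SD replicate 3) to 0.43 (replicate 1) and BEIIa, lux versus elf3-1 elf3-2, ZT14 SD, from −1.94 (elf3 ZT14 SD replicate 2) to 0.26 (replicate 1). The correlation of lux and elf3 effects (0.301) was 0.446 over genes of at least 10 CPM; that of phyB and elf3 effects (0.154) reversed to −0.015 over those genes and to −0.116 on log2(TPM + 1).

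Leaving out 1 library at a time gave these ranges, with the libraries that moved a count beyond 1.5 times named beside that count in the text above. For elf3: 2 to 2553 at ZT6 LD (reported 774), 1 to 487 at ZT6 SD (reported 49), 0 to 2 at ZT14 LD (reported 0), 71 to 1238 at ZT14 SD (reported 408), 21 to 138 at ZT18 LD (reported 177), 65 to 128 at ZT18 SD (reported 157), 0 to 66 for the interaction (reported 0). For phyB: 0 to 1 at ZT6 LD (reported 0), 0 to 14 at ZT6 SD (reported 0), 0 to 17 at ZT14 LD (reported 0), 0 to 1223 at ZT14 SD (reported 4), 467 to 891 at ZT18 LD (reported 1953), 122 to 169 at ZT18 SD (reported 541), 0 to 11 for the interaction (reported 4). For day length: 0 to 4011 at ZT2 (reported 772), 0 to 1002 at ZT6 (reported 0), 9 to 1030 at ZT10 (reported 411), 1494 to 2442 at ZT18 (reported 3596), 260 to 5914 at ZT24 (reported 2168). The averages, the day length result over all times and at ZT14, time of day, the lux comparisons and the list tests (42 to 50) stayed within 1.5 times of the reported count. Leaving out 1 of the 2 elf3 libraries at ZT14 LD leaves a lone library, which is assumed to vary like the other groups. Correlations ranged from 0.239 to 0.397 (lux and elf3) and from 0.044 to 0.208 (phyB and elf3).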

Other observations

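The test of elf3-1 elf3-2 markers in lux was chosen after the results were seen. The hypothesis was that lux shares the expression change of elf3-1 elf3-2, as 2 members of the same complex would. On the ZT18 markers of elf3-1 elf3-2 the lux libraries at ZT14 SD lay at 0.7 to 0.77, where the highest WT library of that group lay at 0, and at 0 on the phyB markers. Of the 47 markers, 46 of them higher in elf3-1 elf3-2, 25 passed in lux against WT in the same direction and 0 in the opposite one. Of all 28912 tested genes 9424 passed as higher in lux and 6812 as lower, so many would pass without a shared change. The values may therefore reflect a change common to loss of LUX and loss of ELF3, although the tissue markers of lux leave the size of that change open.

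In the values themselves, the 2 closest libraries of the series are replicate 3 of WT at ZT2 LD and replicate 3 of WT at ZT2 SD, with a mean chi-square of 2.94 per gene, where the lowest between libraries of 1 group was 8.14. Also below it were replicate 1 of elf3-1 elf3-2 at ZT14 SD with replicate 3 of WT at ZT14 LD (7.96) and replicate 2 of WT at ZT6 SD with replicate 1 of WT at ZT10 LD (7.97). Of the 57 libraries not doubted, 2 lay nearer another group than their own, replicates 1 and 2 of elf3-1 elf3-2 at ZT18 SD, which lay nearer elf3-1 elf3-2 at ZT14 SD. Libraries with the same replicate number in different groups had a mean correlation of residuals of 0.034, against −0.017 for different numbers, and 188 of 876 pairs with the same number lay above 0.1, against 194 of 1752 with different numbers.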
